A study of Homo sapiens with 4 samples.

How the data were processed

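Gene expression was measured in MCF7 cells, an established human breast cancer line of luminal type that expresses the estrogen receptor. The cells had been treated for 12 h with 10 µM NB001 or with DMSO, the solvent used as vehicle control. NB001 is given by its code name, and the labels do not say what it acts on. Each treatment has 2 samples that the labels call biological replicates, without saying whether they came from separate cultures. Limma's p-values for probe sets and genes therefore measure the spread between these samples, which may be partly technical. Per the labels' protocols, total RNA was amplified and labelled with biotin by in vitro transcription from the 3′ end and hybridised to Affymetrix expression arrays, 1 array per sample.

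The deposited table holds the authors' log2 signals of 22277 probe sets on each of the 4 arrays. The signals were made with MAS5, per the submitters' processing notes; its version is not given in the sources used here. The values themselves show the scaling. After conversion to a linear scale, the mean signal with 2% of the probe sets trimmed at each end lay between 500.17 and 500.18 on every array. Linear signals had a floor of 1, where the log2 value is 0. It was listed for 373 and 426 probe sets on the NB001 arrays and for 210 and 264 on the DMSO arrays. The deposited values were not centred per gene. They come without detection calls, so a dim probe set cannot be called present or absent. MAS5 scales each array by a single factor and gives noisy values at low signal, which makes fold changes of dim probe sets uncertain. For arrays, their number limits the precision, here 2 per group.

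Probe sets were named through the platform's annotation table. Of the 22277 probe sets, 19070 had 1 gene symbol, 1043 had several and 2164 had none, and 62 were control probe sets. The gene identifiers of 19058 of the 19070 were found in a RefSeq gene table of assembly GRCh38.p14, which was used for names and for the order of neighbouring genes alone. No gene was named from a probe set with several symbols. The files name no genome build, and no coordinates are given.

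The 22215 probe sets other than controls were filtered on their mean log2 value over the 4 arrays, at or above the 40th percentile (5.08), which left 13329. The deposited log2 values were fitted as they were in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend, two-sided, with no block. The fit has 2 residual degrees of freedom per probe set, and 10.4 with the prior taken from all probe sets. A probe set was called changed at a Benjamini-Hochberg adjusted p under 0.05. Errors of fold changes are limma's moderated standard errors (SE), and errors of group means are standard deviations (SD, n = 2). An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so none is reported for single genes. Each of the 7945 genes with a tested probe set of 1 symbol was represented by the probe set with the highest mean value.

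Before the data were examined, 32 gene lists were fixed (28 of pathways or gene families and 4 of markers of other cell types), together with the tests and the alternatives. Each list with at least 5 measured members was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 28 lists that qualified. The test was repeated with the correlation estimated from the data. At the preset correlation camera compares a list's genes with the other genes. Its p-values then take their degrees of freedom from the number of genes, not of samples. Members called changed were counted after adjustment over all genes tested and after adjustment over the list alone. Genes named in the text were also set by a rule written beforehand. They are the 12 genes with the largest rise and the 12 with the largest fall among genes called changed whose groups did not overlap, the 4 members with the smallest p from each list, and a fixed set of reference genes. Genes outside this rule are said to have been chosen after their values were seen.

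The fit was also run on simulated data with the real means and with spreads drawn from the fitted intensity trend, with independent noise. A small share of the 13329 probe sets was changed, so the shares called may differ from those in the real data. The fit called 29.2% of the probe sets changed by a log2 value of 0.5 and 56.0% of those changed by 1. It called 81.6% of those changed by 1.5 and 80.4% of those changed by 2. Of its calls, 6.16% were false, and with no change simulated it made 0 calls. Alternatives covered the filter, the scaling between arrays, the variance model, a replicate block, each array left out in turn, a 2-fold threshold, the mean over a gene's probe sets and the estimated correlation. Control probe sets stayed out of the tests of genes and are described separately.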

Results

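The data describe the transcriptome of MCF7 breast cancer cells after 12 h with 10 µM NB001 or with the vehicle DMSO, with 2 arrays per group. The comparison asks which transcripts differ between treated and vehicle cells. The 4 arrays had median log2 signals of 6.30 and 6.24 (NB001) and 6.34 and 6.35 (DMSO). Over the 13329 probe sets tested, replicate arrays correlated across probe sets at r = 0.985 (NB001) and r = 0.982 (DMSO), against 0.967 to 0.968 between groups; probe sets are not independent replicates. The median absolute log2 difference was 0.148 and 0.155 between replicates and 0.283 to 0.288 between groups.

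NB001-treated cells differed from vehicle cells at many genes in both directions. The genes with the largest rises included TNS3, which encodes a tensin of focal adhesions (8.17-fold higher), SCNN1A, the alpha subunit of the epithelial sodium channel (7.55-fold higher), and the transcriptional repressor BCL6 (4.41-fold higher). The largest falls included the interferon-induced genes IFI27 (7.08-fold lower) and IFI6 (5.34-fold lower) and MSMB, which encodes a secreted microseminoprotein (6.16-fold lower). Of 7945 genes tested, 900 rose and 803 fell at an adjusted p under 0.05 (limma), with a median absolute log2 fold change of 0.52 among the genes called. Of these, 120 rose and 92 fell at least 2-fold.

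At the level of probe sets, 2813 of 13329 (21.1%) changed, 1474 higher and 1339 lower. Both NB001 arrays lay on one side of both DMSO arrays for all 2813. Such separation held for 61.5% of all tested probe sets, where chance gives 33.3%. The higher share of the calls was 52.4%, and it was 64.9% when each array was centred on its median instead. A change of at least 2-fold was called at 437 probe sets, and at 162 with 64 added to the linear signal (chosen after the data were seen), which shrinks folds of dim probe sets. Without the intensity trend in the variance model 0 probe sets passed limma's adjusted threshold, with 3802 at an unadjusted p under 0.05 against 4553 with the trend.

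**Figure D1:**
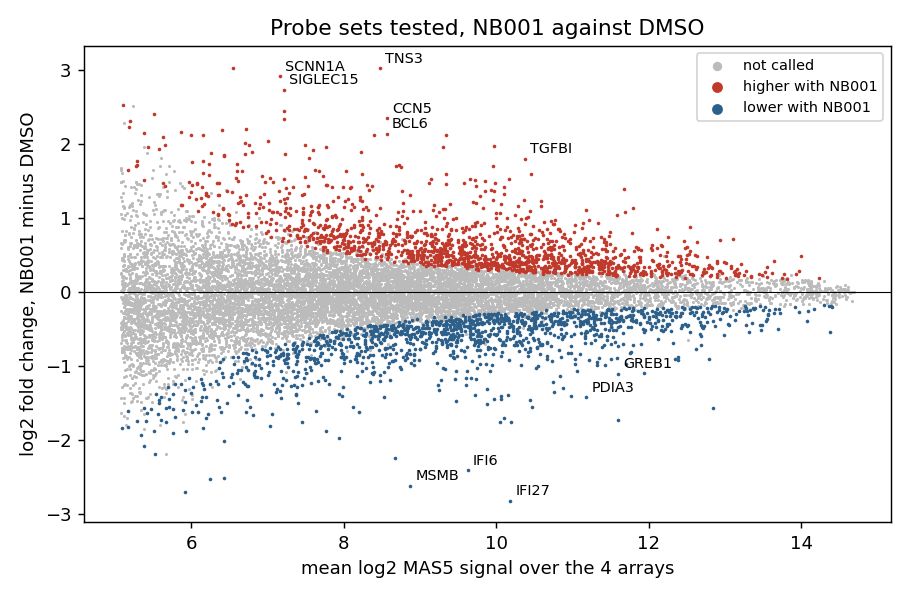
Log2 fold change (NB001 minus DMSO, vertical axis) against mean log2 MAS5 signal over the 4 arrays (horizontal axis) for the 13329 probe sets tested; each point is a probe set, coloured where limma's adjusted p was under 0.05. Of the 2813 coloured points, 1474 lie above 0 and 1339 below, and dim probe sets needed larger fold changes to be called.

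TNS3 had a mean log2 signal of 9.99 ± 0.02 with NB001 and 6.96 ± 0.18 with DMSO (SD, n = 2), a log2 fold change of 3.03 ± 0.15 (SE; limma adjusted p = 2.1e-06). SCNN1A rose by 2.92 ± 0.26 on the log2 scale. SIGLEC15, which encodes a lectin that binds sialic acid, rose by 2.74 ± 0.22, and the ephrin receptor gene EPHA4 by 2.45 ± 0.24. CCN5, a matricellular protein gene, rose from 7.39 ± 0.37 to 9.74 ± 0.05, which is 5.11-fold. BCL6 rose from 7.49 ± 0.14 to 9.63 ± 0.02 and DEPDC1 from 7.33 ± 0.01 to 9.45 ± 0.18. GABBR2, a subunit gene of the GABA type B receptor, rose by 2.20 ± 0.29, but its call was lost when its probe sets were averaged (log2 fold change 1.21). CFAP70, HSPG2, VTCN1 and LAMB3 completed the 12 largest rises. These 4 were dim, with DMSO means between 4.03 and 4.94. HSPG2, the perlecan gene, had a log2 fold change of 2.16 ± 0.55, which was 1.21 without DMSO replicate 2, and LAMB3, a laminin chain gene, had 2.12 ± 0.52 and 1.26. CFAP70 lost its call without NB001 replicate 2, as did VTCN1 without NB001 replicate 1.

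Among the 12 largest falls, IFI27 went from a log2 signal of 11.60 ± 0.08 with DMSO to 8.77 ± 0.21 with NB001 (SD, n = 2), a log2 fold change of -2.82 ± 0.11 (SE; limma adjusted p = 1.1e-06). MSMB went from 10.18 ± 0.11 to 7.55 ± 0.02 and IFI6 from 10.83 ± 0.22 to 8.42 ± 0.09. S100A8, which encodes a calcium-binding protein of the calprotectin complex, was 4.06-fold lower, with a log2 fold change of -2.02 ± 0.32, and the nuclear receptor gene NR2E3 had -1.88 ± 0.37. PODNL1 had -2.53 ± 0.53, which was -1.57 without NB001 replicate 1. The NB001 means of NR2E3 (4.99) and PODNL1 (4.98) were below the filter's mean of 5.08. TOM1, RUNX1T1, ZNF675, HP1BP3, FGF18 and DOHH had NB001 means between 4.18 and 4.80, below the filter's mean of 5.08, and each lost its call without at least 1 of the arrays. These 6, HSPG2 and LAMB3 also lost it without the filter, and TOM1 and DOHH with quantile or cyclic loess normalization. Folds of dim genes shrank, with the calls kept, when 64 was added to the linear signal (chosen after the data were seen). Examples are S100A8 (-1.16), NR2E3 (-0.92), PODNL1 (-1.30) and GABBR2 (1.36). Across all probe sets other than controls, dim ones leaned lower with NB001. Their median log2 fold change was -0.16 in decile 5 by signal, against 0.01 in decile 10.

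**Figure D2:**
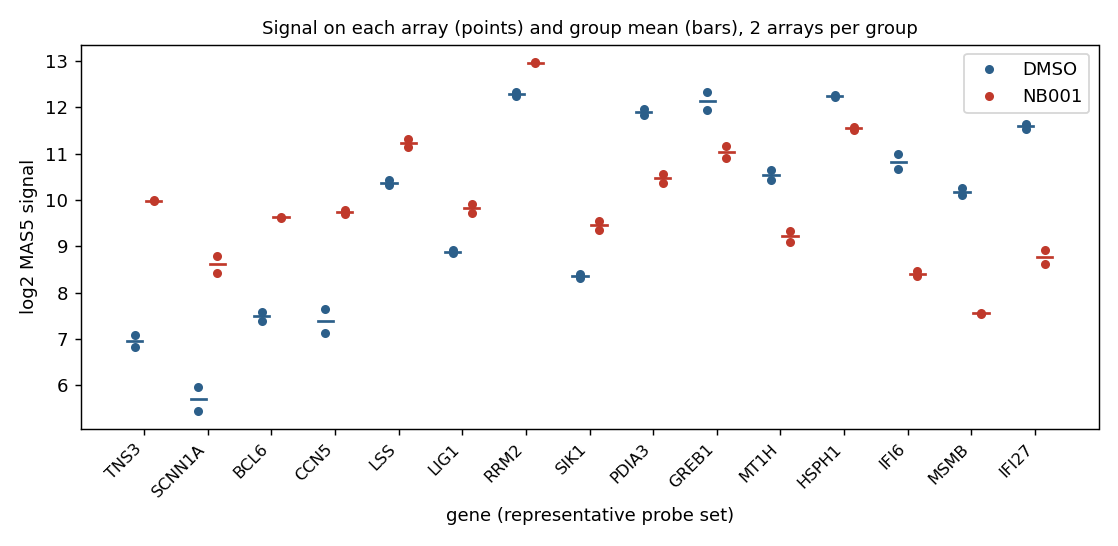
Log2 MAS5 signal (vertical axis) of 15 genes (horizontal axis) on each array; points are the 2 arrays per group and bars their mean, DMSO in blue and NB001 in red. For all 15 genes both NB001 points lie on one side of both DMSO points, with TNS3 moving from 6.96 to 9.99 and IFI27 from 11.60 to 8.77.

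Control transcripts on the arrays also differed between the groups. The 24 probe sets for poly-A RNA spike-ins, which are added to the RNA before labelling, were lower on both NB001 arrays than on both DMSO arrays, with a median log2 difference of -2.10 (range -2.90 to -1.22). The 18 probe sets for hybridization spike-ins, which are added after labelling, had a median of -0.52 (range -1.23 to -0.12) and were likewise all lower. Probe sets for 18S and 28S ribosomal RNA had medians of -0.76 and -0.44. The ratio of 3′ to 5′ control probe sets, a sign of RNA integrity, had a mean log2 value of 0.76 with NB001 and 0.80 with DMSO for GAPDH, and of 3.78 and 4.00 for ACTB. For STAT1 the mean log2 ratio was 8.17 with NB001 (9.30 and 7.04) and 5.08 with DMSO (4.96 and 5.21), so the groups did not overlap. The 5′ probe set of STAT1 was dim, with mean log2 signals of 2.40 and 5.60, while its 3′ probe set had 10.58 and 10.68. The labels name no batch, so batch and treatment cannot be told apart.

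**Figure D3:**
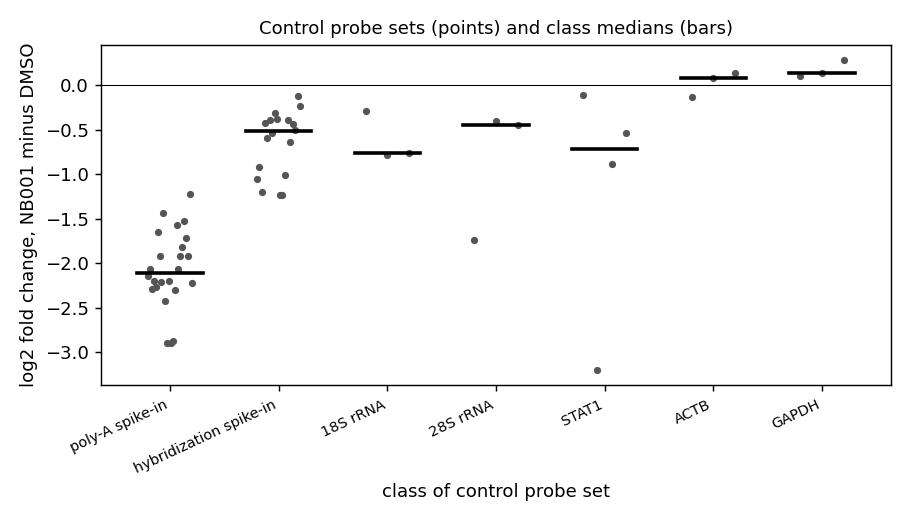
Log2 difference (NB001 minus DMSO, vertical axis) of control probe sets by class (horizontal axis); points are probe sets and bars class medians. All 24 poly-A spike-in points and all 18 hybridization spike-in points lie below 0, with medians of -2.10 and -0.52, while the medians of ACTB and GAPDH are 0.09 and 0.14.

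Of the 28 lists tested, 7 shifted with camera's preset correlation, 2 higher and 5 lower. With an estimated correlation 0 of the 28 passed, and 4 had an unadjusted camera p under 0.05. The latter test rests on the 2 residual degrees of freedom of the fit, the former on the number of genes. The spike-in controls above were lower with NB001 as well, beside each of these lists.

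Metallothionein genes, which encode small metal-binding proteins induced by zinc and other metals, fell together. Of 8 measured members of this list 7 fell, 0 rose and 1 did not pass (8 fell when adjusted over the list alone), with a median log2 fold change of -0.60 (camera adjusted p = 1.0e-05; adjusted p = 0.302 with an estimated correlation). MT1H went from 10.54 ± 0.15 with DMSO to 9.22 ± 0.18 with NB001 (SD, n = 2), a log2 fold change of -1.32 ± 0.12 (SE). MT1X had -0.62 ± 0.07 and MT2A -0.52 ± 0.07. Metallothionein sequences are alike, and these 3 probe sets belong to a design class that can cross-hybridise. SLC30A1, a zinc exporter gene, had -0.57 ± 0.11.

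Interferon-stimulated genes were lower with NB001. Of 15 measured members 7 fell, 0 rose and 8 did not pass (7 fell when adjusted over the list alone), with a median log2 fold change of -0.56 (camera adjusted p = 6.6e-05; adjusted p = 0.302 with an estimated correlation). Beside IFI27 and IFI6, the ubiquitin-like modifier gene ISG15 fell by 0.56 ± 0.08 and IFITM1, which encodes a membrane protein that restricts viral entry, fell by 0.64 ± 0.11.

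Heat shock genes, which encode cytosolic and mitochondrial chaperones, were also lower. Of 19 measured members 9 fell, 0 rose and 10 did not pass (9 fell when adjusted over the list alone), with a median of -0.25 (camera adjusted p = 1.7e-04; adjusted p = 0.302 with an estimated correlation). HSPE1, the mitochondrial co-chaperonin, fell by 0.59 ± 0.07 on the log2 scale, DNAJA1 by 0.45 ± 0.07 and CHORDC1 by 0.68 ± 0.10. HSPH1 had -0.70 ± 0.07 at its brighter probe set, but another probe set rose by 1.18, and the mean over both was 0.24. HSP90AA1 and HSPA4 also had probe sets called in both directions. With the mean over each gene's probe sets 1 member of the list rose and 9 fell. HSPA1A had no probe set with its symbol alone.

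DNA replication and G1/S genes rose. Of 36 measured members 13 rose, 0 fell and 23 did not pass (14 rose when adjusted over the list alone), with a median of 0.22 (camera adjusted p = 1.9e-04; adjusted p = 0.302 with an estimated correlation). LIG1, the replicative DNA ligase, rose by 0.93 ± 0.11, and CCNE1, cyclin E1, by 0.83 ± 0.15. The replicative helicase gene MCM2 rose by 0.71 ± 0.09. RRM2, a ribonucleotide reductase subunit gene, rose by 0.68 ± 0.06, or 0.42 as the mean over its probe sets. E2F1 had -0.27 ± 0.33. Mitosis and G2/M genes did not shift as a list, with 5 of 38 members higher, 1 lower and a median of 0.04 (camera adjusted p = 0.377). The 5 rises were 3 without NB001 replicate 2 or without DMSO replicate 2, and the fall lost its call without any 1 of the 4 arrays. Their called members included PRC1 (0.49 ± 0.06), KIF2C (0.68 ± 0.10) and CDC25C (0.64 ± 0.14, lost without NB001 replicate 2). MKI67, the proliferation marker Ki-67, had 0.05 ± 0.09 at its brightest probe set, with 1 of its 4 probe sets called higher, and CCNB1 had -0.12 ± 0.08.

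Genes of cholesterol and fatty acid synthesis rose as well. Of 24 measured members 9 rose, 0 fell and 15 did not pass (9 rose when adjusted over the list alone), with a median of 0.24 (camera adjusted p = 0.0024; adjusted p = 0.327 with an estimated correlation). The 9 rises were 6 without DMSO replicate 1 and 5 without NB001 replicate 2 or without DMSO replicate 2, with the list call kept. SQLE, squalene epoxidase, rose by 0.56 ± 0.07, TMEM97 by 0.58 ± 0.08 (0.93 as the mean over its probe sets) and the fatty acid synthase gene FASN by 0.69 ± 0.16, the last losing its call without DMSO replicate 1. LSS, lanosterol synthase, had 0.86 ± 0.09, but 0.39 and no call as the mean over its probe sets. HMGCS1 had 0.18 ± 0.11 and INSIG1 -0.14 ± 0.08, neither called, though INSIG1 had 0.38, past the threshold, as the mean over its probe sets. LDLR had no probe set with its symbol alone.

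Polyadenylated and replication-independent histone genes fell. Of 9 measured members 4 fell, 0 rose and 5 did not pass (5 fell when adjusted over the list alone), with a median of -0.29 (camera adjusted p = 0.0026; adjusted p = 0.460 with an estimated correlation). H2AC6 had a log2 fold change of -1.03 ± 0.12 and H2BC5 had -0.61 ± 0.08. The probe sets of H2BC5 and H2BC6 belong to the design class that can cross-hybridise. With the mean over each gene's probe sets 1 member rose and 4 fell.

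Estrogen receptor targets moved in both directions, with more falls than rises. Of 31 measured members 10 fell, 3 rose and 18 did not pass (11 and 3 when adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.0038; adjusted p = 0.327 with an estimated correlation). The median was -0.13 with the filter at the 60th percentile. GREB1, a cofactor gene induced by estrogen, went from 12.14 ± 0.27 with DMSO to 11.04 ± 0.17 with NB001 (SD, n = 2), which is 2.15-fold lower. EGR3 was 2.06-fold lower, MYBL1 1.68-fold lower and RAB31 1.55-fold lower, while CTSD, the cathepsin D gene, was 1.71-fold higher. TFF1 (-0.03 ± 0.06), PGR (-0.44 ± 0.27) and CCND1 (-0.13 ± 0.07) did not pass, nor did ESR1, the estrogen receptor gene itself (-0.11 ± 0.07). The TFF1 means (14.42 with NB001, 14.45 with DMSO) lay near the highest signals of the arrays (14.65 to 14.76). Whether folds shrink there was not tested. CCND1 had 0.21, past the threshold, as the mean over its probe sets.

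**Figure D4:**
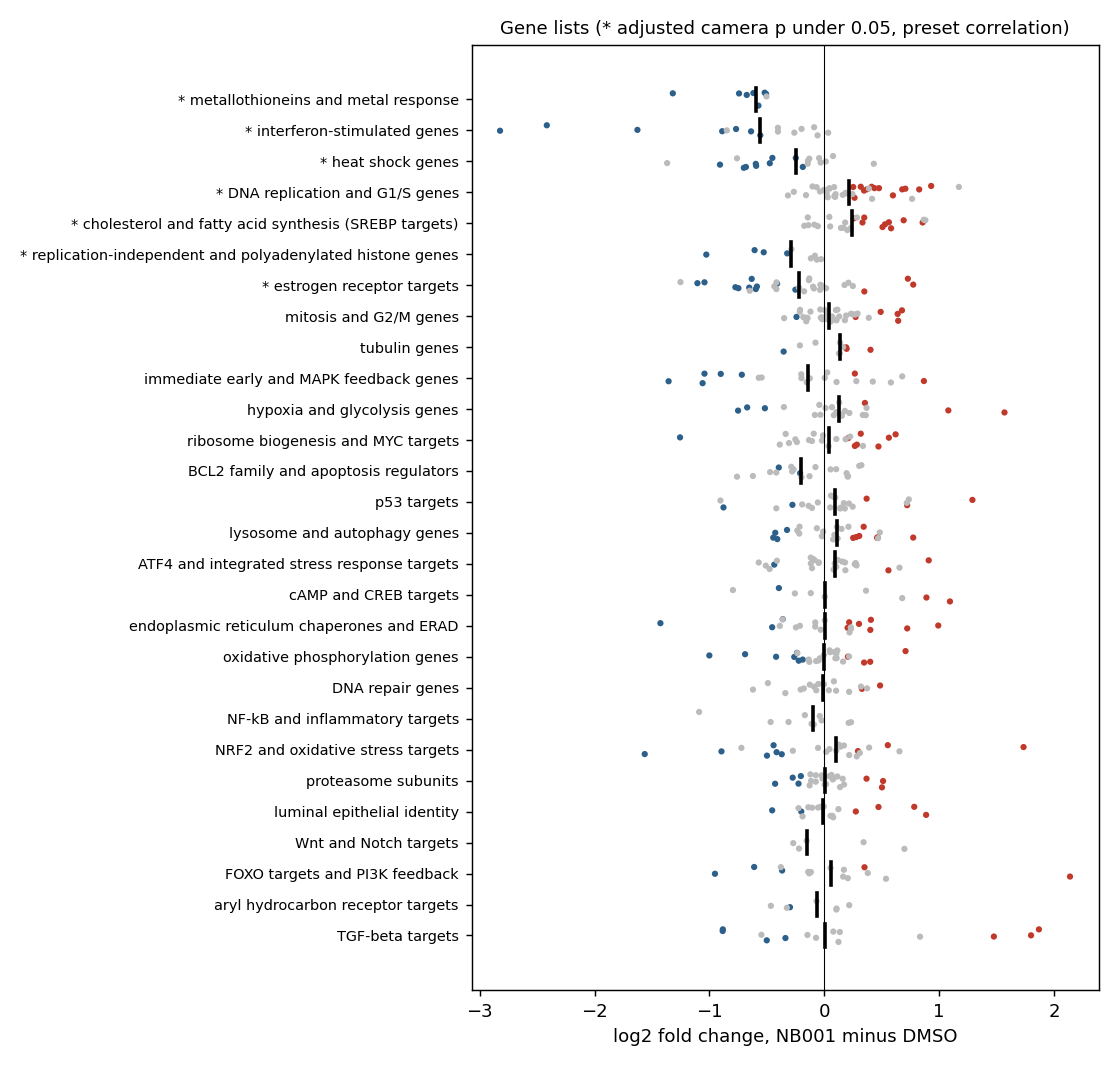
Log2 fold change (NB001 minus DMSO, horizontal axis) of the measured members of the 28 gene lists tested (vertical axis); points are genes, coloured where limma's adjusted p was under 0.05 (red higher, blue lower), black bars are list medians, and asterisks mark the 7 lists that passed camera with a preset correlation. The list medians run from -0.60 for metallothioneins to 0.24 for cholesterol and fatty acid synthesis.

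Several lists held strongly changed members that went opposite ways, with no shift of the list. In TGF-beta targets, 3 of 14 members rose and 4 fell (camera adjusted p = 0.965, negative in direction against a median of 0.003 and a mean of 0.21). TGFBI, a secreted matrix protein gene, was 3.48-fold higher and SKI, a corepressor of SMAD proteins, 3.65-fold higher, while ID3 was 1.84-fold lower and ID2 1.42-fold lower, with a log2 fold change of -0.98 as the mean over its probe sets. With 64 added to the linear signal SKI had a log2 fold change of 1.15. Among endoplasmic reticulum chaperones and ERAD genes 7 of 21 rose and 3 fell (adjusted p = 0.780), with 4 rises without NB001 replicate 1 or without DMSO replicate 2. PDIA3, a protein disulfide isomerase gene, was 2.69-fold lower, whereas HSP90B1 was 1.99-fold higher and CRELD2 1.65-fold higher. HSPA5 had 0.20 ± 0.06 and lost its call without each of 3 of the arrays, NB001 replicate 2 and both DMSO replicates. Immediate early and MAPK feedback genes had 2 of 20 higher and 5 lower (adjusted p = 0.512), with PHLDA1 2.56-fold lower, KLF6 1.65-fold lower and the phosphatase gene DUSP4 1.82-fold higher. The rises were 1 without DMSO replicate 1. FOXO targets and PI3K feedback genes had 2 of 15 higher, BCL6 among them, and 3 lower (adjusted p = 0.865), with 1 rise without NB001 replicate 1.

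Genes of oxidative stress and metabolism were mixed too. NRF2 and oxidative stress targets had 3 of 23 higher and 6 lower (camera adjusted p = 0.865; median 0.10, mean -0.01, negative in direction). TXNRD1, thioredoxin reductase, rose by 0.55 ± 0.07, AKR1C2 had -0.50 ± 0.07 and HMOX1, heme oxygenase, had -1.56 ± 0.30, which lost its call without DMSO replicate 2 and was -0.99 with 64 added to the linear signal. NQO1 had 0.22 ± 0.09 at its brightest probe set and did not pass, while its other 2 probe sets were called higher (0.58 and 0.31). Hypoxia and glycolysis genes had 3 of 23 higher and 3 lower (adjusted p = 0.552). EGLN3, an oxygen-sensing hydroxylase, was 2.97-fold higher (log2 fold change 1.57, or 1.003 with 64 added to the linear signal) and P4HA1, a collagen prolyl hydroxylase subunit gene, 1.68-fold lower. Oxidative phosphorylation genes had 4 of 27 higher and 7 lower (adjusted p = 0.865), with SDHA 1.63-fold higher and NDUFB3 1.61-fold lower. The falls were 4 without NB001 replicate 2 and 3 without DMSO replicate 1, and the rises were 2 without NB001 replicate 2. SDHC had -1.001 ± 0.095 at its brightest probe set and -0.29 as the mean over all its probe sets. Lysosome and autophagy genes had 7 of 25 higher (4 without DMSO replicate 2) and 4 lower (adjusted p = 0.560), with CTSD higher and SQSTM1, an autophagy receptor gene, at -0.44 ± 0.09. Proteasome subunits had 3 of 25 higher and 4 lower (adjusted p = 0.865; 2 lower without NB001 replicate 2 and 1 without DMSO replicate 1), with PSMD2 at 0.51 ± 0.07 and PSMC6 at -0.43 ± 0.06.

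The lists of p53 targets, ATF4 targets, cAMP and CREB targets, and ribosome biogenesis and MYC targets did not pass the list test. Of 23 p53 targets 3 rose and 2 fell (camera adjusted p = 0.560). The falls, PLK2 (-0.28 ± 0.07) and POLH (-0.88 ± 0.26), both lost their call without DMSO replicate 1, and 1 of them did so without each other array; GDF15 (0.37 ± 0.11) lost its call without each array but NB001 replicate 1. POLH and GDF15 also lost it without the filter, GDF15 with quantile normalization too, and POLH had -0.56 with 64 added to the linear signal. DDB2, a DNA damage sensor gene, rose by 0.72 ± 0.11, while CDKN1A had 0.14 ± 0.09 and MDM2 had -0.90 ± 0.31, neither called. Of 27 ATF4 and integrated stress response targets 2 rose and 1 fell (adjusted p = 0.726), with DDIT4 1.88-fold higher, GARS1 1.47-fold higher and CEBPB 1.35-fold lower; DDIT3 had -0.05 ± 0.22. Of 9 cAMP and CREB targets 2 rose and 1 fell (adjusted p = 0.780). SIK1, a salt-inducible kinase gene, was 2.13-fold higher, CREM had 0.89 ± 0.18 but no call as the mean over its probe sets (0.46), and the adenylyl cyclase gene ADCY1 had -0.40 ± 0.09, lost without NB001 replicate 2 and without DMSO replicate 1. Of 23 ribosome biogenesis and MYC targets 7 rose and 1 fell (adjusted p = 0.552; 3 rose without DMSO replicate 1, 4 without NB001 replicate 2 and 4 without DMSO replicate 2), with the nucleolar gene FBL 1.54-fold higher and TAF1D 2.39-fold lower. NOP16 had 0.56 ± 0.08 at its brightest probe set but -0.28 as the mean over its probe sets. MYC had 0.27 ± 0.08, a call lost without any 1 of the 4 arrays.

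Of 19 BCL2 family genes and apoptosis regulators 0 rose and 2 fell (camera adjusted p = 0.560; 0 when adjusted over the list alone), and both, PMAIP1 (-0.40 ± 0.11) and MCL1 (-0.21 ± 0.06), lost their call when arrays were centred on their median and without NB001 replicate 1 or either DMSO replicate, MCL1 also without NB001 replicate 2. As means over their probe sets they had -0.79 and -0.58, both called. Of 10 tubulin genes 3 rose and 1 fell (adjusted p = 0.512). TUBB2A rose by 0.40 ± 0.08 and TUBA1B (0.19 ± 0.06), TUBB (0.19 ± 0.06) and TUBB6 (-0.35 ± 0.09) were the other calls. Of these 4 calls, that of TUBB2A alone was kept without NB001 replicate 2 and without DMSO replicate 2, and without NB001 replicate 1 TUBA1B and TUBB lost theirs, as TUBB did without DMSO replicate 1. TUBA1B and TUBB also lost it without the filter and as means over their probe sets (0.15 and 0.12). Of 19 DNA repair genes 2 rose, FANCI (0.33 ± 0.07) and PALB2 (0.49 ± 0.12, lost without DMSO replicate 1), and 0 fell (adjusted p = 0.865; median and mean -0.01, positive in direction). Of 18 luminal identity genes 4 rose and 2 fell (adjusted p = 0.865; median -0.01, mean 0.07, positive in direction), with 1 fall without NB001 replicate 2 or without DMSO replicate 1. The mucin gene MUC1 was 1.72-fold higher and ELF3 1.85-fold higher, while XBP1 was 1.37-fold lower. KRT18 had -0.03 ± 0.06. Of 7 aryl hydrocarbon receptor targets 1 fell, NFE2L2 (-0.30 ± 0.07, lost when arrays were centred on their median and without NB001 replicate 1 or DMSO replicate 2), and 0 rose (adjusted p = 0.865). Of 10 NF-kB and inflammatory targets 0 were called by limma, with 1 at an unadjusted p under 0.05 (NFKBIA, 0.21 ± 0.09; list adjusted p = 0.865). Of 5 Wnt and Notch targets 0 were called over all genes, with 2 at an unadjusted p under 0.05, HEY1 (0.70 ± 0.24) and HES1 (0.34 ± 0.12), which are also the 2 called when adjusted over the list alone (list adjusted p = 0.865; median -0.15, mean 0.08, positive in direction).

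Markers of other cell types were mostly below the filter on dim probe sets, and their 4 lists had too few members for a list test. Of 14 fibroblast and mesenchymal markers 4 were above it. FN1, fibronectin, rose by 0.70 ± 0.10, while VIM (0.43 ± 0.41), COL1A1 (0.22 ± 0.33) and COL3A1 (0.07 ± 0.40) did not pass. Of the 6 basal epithelial markers on the array 3 were above it. CAV1, caveolin-1, rose by 0.31 ± 0.07, or 0.52 as the mean over its probe sets, while ACTA2 (-0.16 ± 0.44) and MYLK (0.13 ± 0.41) did not pass. None of the 10 immune and none of the 7 endothelial markers on the array was above the filter. Of 2 common reference genes, GAPDH had 0.25 ± 0.06 (limma adjusted p = 0.012), lost without DMSO replicate 2, and ACTB had -0.07 ± 0.06 and did not pass.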

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

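All 3 tests of the spike-in controls were chosen after their values were seen; those of the interferon and metallothionein genes were set before.

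One signal came from probe sets outside the tests of genes. The control probe set for the middle part of the GAPDH transcript was higher with NB001 by 0.29 on the log2 scale, beyond the spread between replicate arrays.

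The spike-in controls were lower on the NB001 arrays. A single scaling factor per array would move both control classes alike. The poly-A controls were lower than the hybridization controls by a median log2 difference of -1.59, which argues against it. Shifts of the hybridization controls varied with signal. CreX-5 had -0.37 (DMSO mean 14.13) and the dimmer r2-Ec-bioB-3 had -1.23 (9.82). At like DMSO signal, the hybridization control r2-Ec-bioC-5 had -0.64 (10.93) and the poly-A control DapX-3 had -2.14 (10.89). A gap thus remained at like signal. A larger share of mRNA in the total RNA of treated cells, as the whole cause, would leave the hybridization controls near 0, and their median was -0.515. Separate laboratory handling of the groups stays open: all 24 poly-A probe sets separate the groups, the labels give no batch, and handling and treatment cannot be told apart.

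Interferon-stimulated genes were lower with NB001. A difference in scaling or background that depends on signal is argued against as the whole cause, since the list's median was -0.572 after cyclic loess normalization. A culture or handling difference other than NB001 stays open: both NB001 arrays lay below both DMSO arrays for 11 of the 15 members, which either would give. An effect of NB001 itself also stays open and was not tested apart from handling.

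Metallothionein genes were lower with NB001. SLC30A1, which holds no metallothionein sequence, also fell (-0.574), and its fall cannot come from cross-hybridisation with them. It cannot tell how many metallothionein transcripts fell, since a fall of some could be read by the probe sets of others. Cross-hybridisation between their probe sets therefore stays open. A signal-dependent scaling difference is argued against by the median of -0.611 after cyclic loess normalization. A difference in culture, such as metal content of the medium, may also give this pattern: all 8 members separated the groups, and culture and treatment cannot be told apart. An effect of NB001 was not tested separately.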

How the results depend on the processing

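The offsets on the linear signal and the combined settings of variance model were chosen after seeing the data; the other alternatives were planned. Planned pseudocounts for linear values were not run, since the deposited values are log2. The 2813 probe sets called (1474 higher, 1339 lower) became 437 (243 and 194) at a change of at least 2-fold, a stricter criterion by construction; with 16 or 64 added to the linear signal, 374 or 162 changed at least 2-fold. Without an intensity trend 0 were called by limma (0 higher, 0 lower), with 3802 at an unadjusted p under 0.05. On simulated data that model also recovered 0 changed probe sets, but those data were drawn from the trend, which favours this outcome. Without a trend but with the filter at the 60th percentile 2057 were called, 1869 of them among the 2497 main calls still tested. Calls thus returned once dimmer probe sets were left out, which points to noise at low signal. Without a trend and with 64 added to the linear signal 1598 were called (819 higher, 779 lower). Leaving out each array in turn, which leaves 1 array in a group and assumes that it varies like the others, gave 2054 to 2621 calls, 1191 to 1318 higher and 847 to 1311 lower; the 847 were without DMSO replicate 2, and the cause was not tested. Other filters, scalings, robust variances and offsets gave 2212 to 2997 calls. No probe set called in the main setting and still tested changed sign with the other scalings. The remaining settings could not change a sign, since the groups did not overlap at any called probe set.

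Same-numbered samples showed no shared deviation over the probe sets tested (correlation -0.03). The labels do not say whether equal replicate numbers mark a shared day, so a pairing is neither shown nor excluded. With a replicate block 3012 probe sets were called, 2725 of them shared with the main setting.

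The 7 lists (2 higher, 5 lower) passed in every setting except the estimated correlation. That gave 0 (0 higher, 0 lower), with camera adjusted p between 0.302 and 0.967. The estimates were under the preset 0.01 for heat shock (-0.039), cholesterol (-0.039), replication (-0.022), interferon (0.006) and estrogen receptor lists (0.004). This argues against a stronger correlation as the cause there. They were above it for metallothioneins (0.016) and histones (0.097). With an estimated correlation camera has only the 2 residual degrees of freedom of the fit. Of 120 named genes called, 90 kept their call whichever array was left out. As the mean over a gene's probe sets, 4 named genes reversed in sign, where probe sets of the same gene disagree. HSPH1 (0.24) and NOP16 (-0.28) lost their call, while CCND1 (0.21) and INSIG1 (0.38), not called in the main setting, gained a call. A further 12 named genes lost their call without a change of sign. Low signal limits precision: the SD between replicates was 1.41 in decile 2 of probe sets by signal and 0.06 in decile 10.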

Other observations

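Tests of hypotheses in this part were set before their results were seen; the brighter genes, the division of the leading block into histone and other genes, and the tests of symbol families were chosen after.

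Changes among brighter genes (mean log2 value of at least 7.39) went both ways. SERPINA3, a serine protease inhibitor gene, went from a log2 signal of 12.46 ± 0.07 with DMSO to 10.73 ± 0.03 with NB001 (SD, n = 2), which is 3.31-fold lower. The prostaglandin receptor gene PTGER4 was 3.26-fold lower, the adhesion gene AMIGO2 2.98-fold lower, and HS3ST3A1, a heparan sulfate sulfotransferase gene, 3.38-fold lower. ISG20, an interferon-induced exonuclease gene that was not in the list tested, was 2.74-fold lower. Rises included EPAS1, which encodes the hypoxia-inducible factor HIF-2 alpha (3.93-fold higher), the fatty acid transporter gene SLC27A6 (3.89-fold higher), the collagen gene COL5A2 (3.53-fold higher) and OXCT1, an enzyme of ketone body use (3.22-fold higher). These genes were picked for large folds among genes called changed whose groups did not overlap, so both traits follow from the choice. Their limma adjusted p was 1.4e-04 or less.

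Of the 212 genes changed at least 2-fold, 113 had a mean log2 value under 7.39, where the spread between replicates is larger.

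One hypothesis was that replication genes shifted more than mitosis genes. Camera on the 2 lists alone gave p = 0.029 with the replication genes higher, at the preset correlation. The list medians were 0.22 for replication and 0.04 for mitosis. The estimated correlation was 0.12 for the mitosis list, above the preset value, and -0.022 for the replication list. A p at the estimated correlation is not given for this comparison. Whether the 2 lists shifted differently therefore stays undecided.

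Another hypothesis was that a copy number difference between the cultures of the groups may give changes over neighbouring genes. Of 147 blocks of 50 neighbouring genes, 1 passed both bounds, from GPLD1 to HLA-F-AS1, with 0 genes higher and 14 lower, a median log2 fold change of -0.36 and a camera adjusted p of 0.0016. It holds 22 histone genes with a median of -0.56 and 28 other genes with a median of -0.19. All 31 histone genes measured, 22 of them from this block, had a median of -0.42, with 1 higher and 12 lower. A copy number difference and a change of histone transcripts in this cluster cannot be told apart, because the expression values alone give no copy number. Some histone probe sets, such as those of H2BC5 and H2BC6, belong to the design class that can cross-hybridise. How many histone transcripts fell therefore cannot be told.

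Families of genes that share a symbol stem were also tested, and 0 of 79 passed camera's adjusted threshold; the smallest p was that of the MCM family (unadjusted p = 0.0043, adjusted p = 0.339, median 0.22 over 10 genes).

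The 4 arrays can be split into groups of 2 in 3 ways. The real split called 2813 probe sets and the others at most 0. The 3 splits (1 of which called as many as the real one, being the real one) are too few for a share under 0.05. Each other split puts 1 NB001 and 1 DMSO array in both groups. The difference between treatments then enters the spread, so few calls are given whatever its cause.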
